A study of Rattus norvegicus with 7 samples.

How the data were processed

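Total RNA from the cerebellum of 7 female Wistar pups aged 21 days was amplified, labelled with Cy3 and hybridised to 1-colour Agilent rat arrays of design 028279, per the labels and the file headers. RNA purity was judged by absorbance ratios per the labels' protocols, and no measure of RNA integrity is given in the sources used here. Groups were taken from the sample titles, with 4 CTRL and 3 MDD samples. The labels call samples biological replicates, without naming dams or litters.

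The deposited scanner tables hold linear intensities of single spots made with Feature Extraction 10.7.3.1, per the file headers, on a grid built on the rat assembly rn4. Their processed signal is background-subtracted and detrended within the array, and is not normalized between arrays. Other deposited columns are 0 or 1 flags, which are scored by the scanner software per the file headers, and raw median intensities of spot and local background. A further table holds the authors' normalized intensities on a linear scale, with column names that show the group but not which sample. Its method is not given in the sources used here. The mean log2 value over its columns followed the raw median signal with a correlation of 0.999993 across spots and an SD of the difference of 0.0192, against a correlation of 0.977 with the processed signal, so background does not appear to have been subtracted. Its column medians were 311.2, 318.8, 318.0, 315.1, 316.5, 312.1 and 318.0. All 7 arrays carry 1 slide and 1 scan time, so neither is a batch, and the row on the slide was taken from the array positions.

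The main values are log2 of the processed signal minus each array's 75th percentile of it. The 75th percentile ranged from 1140 to 2105 intensity units over the arrays. Control spots and spots flagged as outliers were left out, and spots of one probe were averaged. A probe was kept if well above background on at least 3 of 7 arrays, counting an array when at least 50% of the probe's spots were, which kept 22255 of 30367 probes. The scanner tables paired probes with accessions and not with gene symbols, so symbols were taken by matching the unversioned accession to a RefSeq gene table of the rat assembly GRCr8. This named 18355 probes of 15443 genes. Matching succeeded for 18252 of 19417 curated RefSeq transcripts, 77 of 2339 predicted ones and 0 of 3079 Ensembl transcripts. The rule for named genes had been written for symbols in the scanner tables and was applied to these symbols. The 38 lists hold 1263 members, of which 1250 matched the RefSeq table. For a gene with several kept probes the one with the highest mean over the 7 arrays stood for it, and unnamed probes stood for themselves, which gave 11966 named genes and 8025 unnamed probes. No coordinates are printed, since the grid and the gene table rest on different assemblies. Gene length is the genomic length in the RefSeq table.

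Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default prior, two-sided), with Benjamini-Hochberg adjustment over all 19991 genes and probes and a threshold of 0.05. Fitting left 5 residual degrees of freedom, or 8.37 with the prior. The groups, the test, the alternatives, the 38 gene lists and the rule for named genes were fixed before the data were examined. Named genes are the 12 largest rises and the 12 largest falls among genes with an adjusted p under 0.05, a symbol that does not begin with LOC or RGD, and groups that do not overlap. From each list come up to 6 members that passed, by smallest p, or the 2 with the smallest p where none passed, and from the Wnt and one-carbon lists up to 8 members by smallest p, passing or not. Some genes that this rule names are not reported here. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry as alternatives. Of the 11 lists called with the preset correlation, 0 held with an estimated one, where the smallest adjusted p was 0.670. List medians were also set against 10000 random lists matched on mean signal in 10 bins and gene length in 5 bins. Component 1 and the array quality measures were compared by exact permutation over the 35 splits of the arrays.

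The code was tested on simulated arrays with the sizes of the MDD and CTRL groups and 19991 genes. Of 100 genes changed by 1 on the log2 scale, 36 were recovered, and of 100 changed by 0.5, 0 were, with 0 false calls. Only 200 genes were changed, and their spreads were redrawn around the fitted ones, so these shares do not measure recovery in the data. A shifted list was found, and 0 of the lists sharing no member with it were called. Simulated genes varied independently, so this does not measure false calls of lists whose genes move together.

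Alternatives were quantile normalization, scaling by the median of probes detected on all arrays, normexp background correction with an offset of 50, the authors' deposited table, no filter or a filter requiring all 7 arrays, the mean of a gene's probes, the replicate number or the slide row as a block, each array left out in turn, trend and robust priors, array weights and other thresholds. Normexp was run on the median spot signal and median local background, in place of the mean spot signal foreseen, which is not used here. Removal of each array's trend with gene length, or with gene length and mean signal (loess with a span of 0.5 on named genes), and a test of named genes only were chosen after seeing the data.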

Results

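Cerebellar gene expression was measured on 1-colour microarrays in female Wistar rat pups, aged 21 days, whose dams had been fed different diets. Dams of the control group (CTRL, n = 4 pups) ate a standard diet. Dams of the methyl donor deficiency group (MDD, n = 3 pups) ate a diet without enough folate and vitamin B12 and with less choline, the nutrients that supply methyl groups. Both diets began 1 month before pregnancy and ran to weaning at postnatal day 21. The labels call the samples of a group biological replicates but do not say which pups shared a dam, so p-values measure the spread between pups and not between litters. Each array carried 30367 probes, 74.1% to 79.6% of spots per array were well above background, and 0 were saturated. The number of arrays limits the precision. Values are log2 intensities relative to each array's 75th percentile.

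The single comparison was MDD against CTRL, which asks how early lack of methyl donors changes cerebellar transcripts. The study's title names Wnt signalling as its subject. Transcripts of cytosolic ribosomal proteins and of the mitochondrial respiratory chain were higher in MDD, as were those of a microglial group that included Trem2, Tyrobp and the complement genes C1qa and C1qb (adjusted p = 0.670 for each of these lists with an estimated correlation). Transcripts of granule neurons, of GABA, glycine and glutamate receptors, of synaptic vesicles, of axon guidance and of 2 Wnt lists were lower by camera with a preset correlation, and none of these lists passed with an estimated one (adjusted p = 0.670 to 0.748). Of these lower lists only the granule list kept its call once trends with gene length and signal were removed. Among those that lost it, the median of the beta-catenin list, a Wnt list, did not shrink (-0.187 before, -0.190 after), and the others did. Members of the beta-catenin list called lower went from 6 to 2. The ribosomal and respiratory chain lists kept their call, but their medians shrank, from 0.74 to 0.14 and from 0.64 to 0.20. By limma with Benjamini-Hochberg adjustment, 4077 of 19991 genes and unnamed probes tested changed (20.4%), 2534 higher and 1543 lower. Among the 11966 named genes, 1362 were higher and 799 lower, and 175 and 76 of these changed at least 2-fold. Higher calls made up 62.2% of all calls, and 72.5% with normexp background correction, where 2307 were higher and 875 lower. The groups did not overlap for 36.5% of genes, where chance gives 5.71%.

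Ribosomal protein genes gave the smallest p of the lists. All 74 measured members had a higher mean in MDD, and 61 rose and 0 fell (65 and 0 adjusted over the list alone), with a median log2 change of 0.74. Rplp1, a protein of the ribosomal stalk, stood at 4.54 ± 0.15 (SD, n = 4) in CTRL and 6.24 ± 0.44 (SD, n = 3) in MDD, 3.24-fold higher (log2 1.70, SE 0.21, adjusted p = 0.00967). Rps3 rose 2.44-fold (SE of log2 0.15), Rps21 2.39-fold (SE 0.13) and Rps19 2.19-fold (SE 0.12), each with an adjusted p of 0.00967. Of 68 measured genes of oxidative phosphorylation, 47 rose and 0 fell (53 and 0 adjusted over the list alone), with a median log2 change of 0.64. Uqcr10, a subunit of the cytochrome bc1 complex, rose 2.17-fold (SE of log2 0.13), Cox7a2 of cytochrome c oxidase 2.13-fold (SE 0.14) and Ndufa2 of complex I 2.03-fold (SE 0.14), each with an adjusted p of 0.00967. Camera with a preset correlation called both lists higher (adjusted p = 2.32e-26 for ribosomal proteins and 5.10e-17 for oxidative phosphorylation). With an estimated correlation the adjusted p was 0.670 for both. The size depended on the scaling, since the median was 0.25 with quantile normalization and 0.30 with the authors' deposited table for ribosomal proteins, and 0.18 and 0.26 for oxidative phosphorylation. Among 10000 random lists matched on signal and gene length, 99.97% had a lower median than the ribosomal list, and 100% than that of oxidative phosphorylation. The medians of those random lists were themselves 0.52 and 0.36. The brightest of the 10 signal bins ran from 2.37 to 7.63, so matching on signal is coarse there. Random lists also leave out the correlation between members, estimated at 0.558 and 0.398 for these lists. These percentiles therefore do not exclude a trend with signal and gene length.

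**Figure D1:**
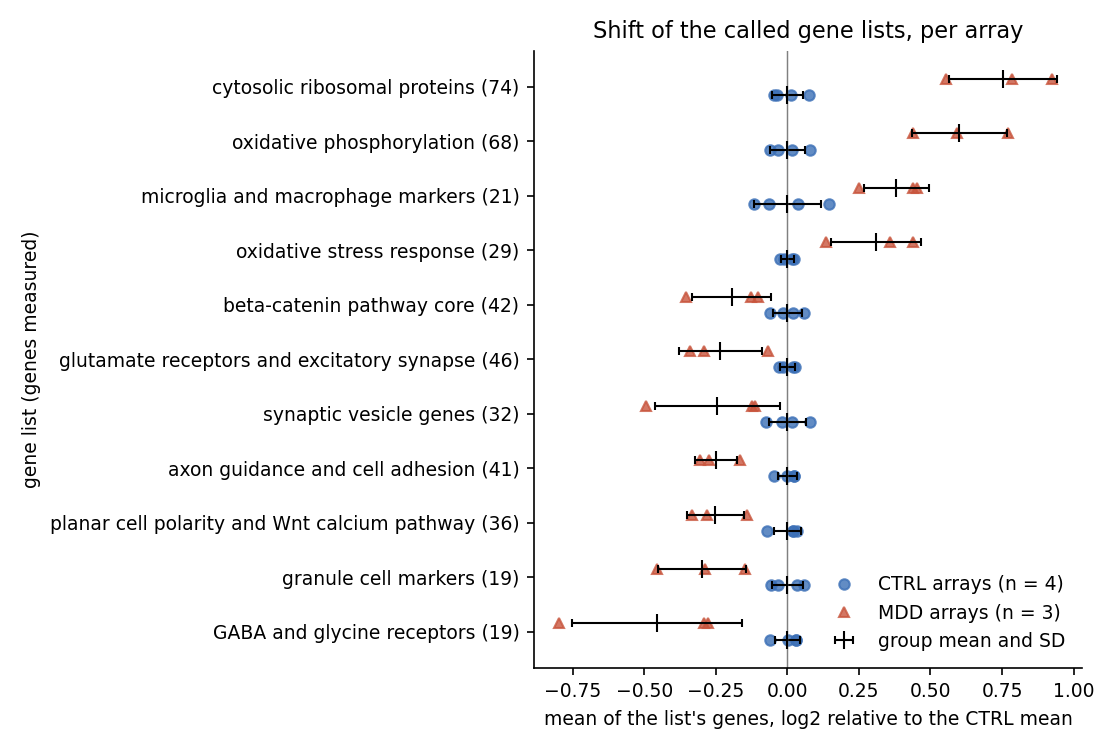
Mean log2 value of the genes of each of the 11 called lists on each array, relative to the CTRL mean, with group means and SD (n = 4 CTRL circles, n = 3 MDD triangles) and the number of genes measured in brackets. On all 3 MDD arrays the ribosomal list lay between 0.55 and 0.93, while the CTRL arrays lay between -0.05 and 0.07.

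Microglial markers rose as a group by camera with the preset correlation, though not with an estimated one. Of 21 measured members, 9 were higher and 1 lower (9 and 2 adjusted over the list alone), with a median log2 change of 0.44. Trem2, a receptor of microglia, was 2.19-fold higher (log2 1.13, SE 0.16, adjusted p = 0.00967). Its signalling partner Tyrobp rose 1.99-fold (SE of log2 0.17, adjusted p = 0.0112), C1qb 1.91-fold, C1qa 1.80-fold and Aif1, which encodes the marker protein Iba1, 1.65-fold. Cx3cr1, the fractalkine receptor, went the other way and was 1.86-fold lower (SE of log2 0.15, adjusted p = 0.0110). Camera gave an adjusted p of 0.00637 with the preset correlation and adjusted p = 0.670 with an estimated correlation. The oxidative stress list had 8 of 29 members higher and 1 lower (8 and 1 adjusted over the list alone), with a median log2 change of 0.31 (camera adjusted p = 0.0176, and adjusted p = 0.670 with an estimated correlation). Glutathione peroxidases led it, Gpx1 at 2.82-fold (SE of log2 0.23, adjusted p = 0.0104) and Gpx4 at 2.29-fold (SE 0.20, adjusted p = 0.0110). Prdx5 rose 1.87-fold and the metallothionein Mt3 1.82-fold, while the catalase gene Cat was 1.67-fold lower. The call for this list was lost with quantile normalization (median 0.14, adjusted p = 0.112), with the authors' deposited table (median 0.17, adjusted p = 0.0599) and without MDD replicate 1 (adjusted p = 0.117).

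The Wnt lists were included because the study's title names the pathway, so their count is not independent evidence of its direction. The list of planar cell polarity and Wnt calcium signalling was lower, with 1 of 36 measured members higher and 5 lower (1 and 4 adjusted over the list alone), a median log2 change of -0.31 and a camera adjusted p of 0.00723 (adjusted p = 0.670 with an estimated correlation). Plcb4, a phospholipase C of Purkinje cells, was 1.69-fold lower (SE of log2 0.12, adjusted p = 0.0104). The cadherin-type polarity gene Celsr3 was 1.67-fold lower, the calcineurin subunit gene Ppp3cb 1.44-fold, Camk2d 1.45-fold and Plcb1 1.45-fold lower. Rac2, a GTPase of blood-derived and microglial cells, was higher (log2 0.58, SE 0.14, adjusted p = 0.0270). In the beta-catenin pathway core, 1 of 42 members was higher and 6 were lower (the same counts adjusted over the list alone), with a median log2 change of -0.19 and a camera adjusted p of 0.0399 (adjusted p = 0.746 with an estimated correlation). The casein kinase genes Csnk1g1 and Csnk1a1 were 2.16-fold and 1.46-fold lower, with adjusted p of 0.0137 and 0.0325. Lef1, a transcription factor that binds beta-catenin, was 1.46-fold lower (SE of log2 0.11, adjusted p = 0.0157), as were the co-repressor gene Tle4 (1.51-fold), Cul1 (1.33-fold) and Dvl3 (log2 -0.59). The ubiquitin ligase subunit gene Rbx1 was 1.65-fold higher. The call for the beta-catenin list was lost without CTRL replicate 3 (adjusted p = 0.0742), without CTRL replicate 4 (adjusted p = 0.0730) and without MDD replicate 1 (adjusted p = 0.119).

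The other 4 Wnt lists were not called. Of 16 receptors and co-receptors, 1 was higher and 3 lower (3 and 3 adjusted over the list alone, median -0.03, and 0.02 with quantile normalization, camera adjusted p = 0.705). Ror1 was 1.44-fold lower, the stem cell receptor gene Lgr5 1.92-fold lower (well above background on 2 of 3 MDD arrays) and Fzd3 1.39-fold lower, and Fzd2 was 1.55-fold higher. Probes of one gene differed in sign for Fzd6, Ror2 and Lrp6, none of which passed over all genes. Fzd6 and Ror2 were among the 3 higher members adjusted over the list alone. Their other probes had log2 changes of -0.66 and -0.08. Of 14 ligands, Wnt2b was 1.91-fold higher (SE of log2 0.25, adjusted p = 0.0345, well above background on 3 of 4 CTRL arrays) and 0 were lower (0 and 0 adjusted over the list alone, median 0.13, camera adjusted p = 0.526). Wnt7a, which granule neurons make, had a log2 change of 0.29 (SE 0.18, adjusted p = 0.273). Of 8 secreted inhibitors 0 passed (0 and 0 adjusted over the list alone, median 0.03, camera adjusted p = 0.657), with Dkk3 at a log2 change of 0.01 (SE 0.15, adjusted p = 0.963). Of 23 target genes, 2 were higher and 4 lower (2 and 4 adjusted over the list alone, median -0.29, but -0.16 with normexp and -0.08 with the authors' deposited table, camera adjusted p = 0.307). Twist1 (well above background on 2 of 4 CTRL arrays) was 2.24-fold and Birc5 1.36-fold higher, whereas Vegfa was 1.49-fold and Nrcam 2.02-fold lower. Over the kept probes of a gene, log2 changes ran from -1.13 to -0.22 for Vegfa and from -1.01 to -0.20 for Nrcam. Axin2, a common readout of beta-catenin activity, had a log2 change of -0.61 (SE 0.24, adjusted p = 0.0959).

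**Figure D2:**
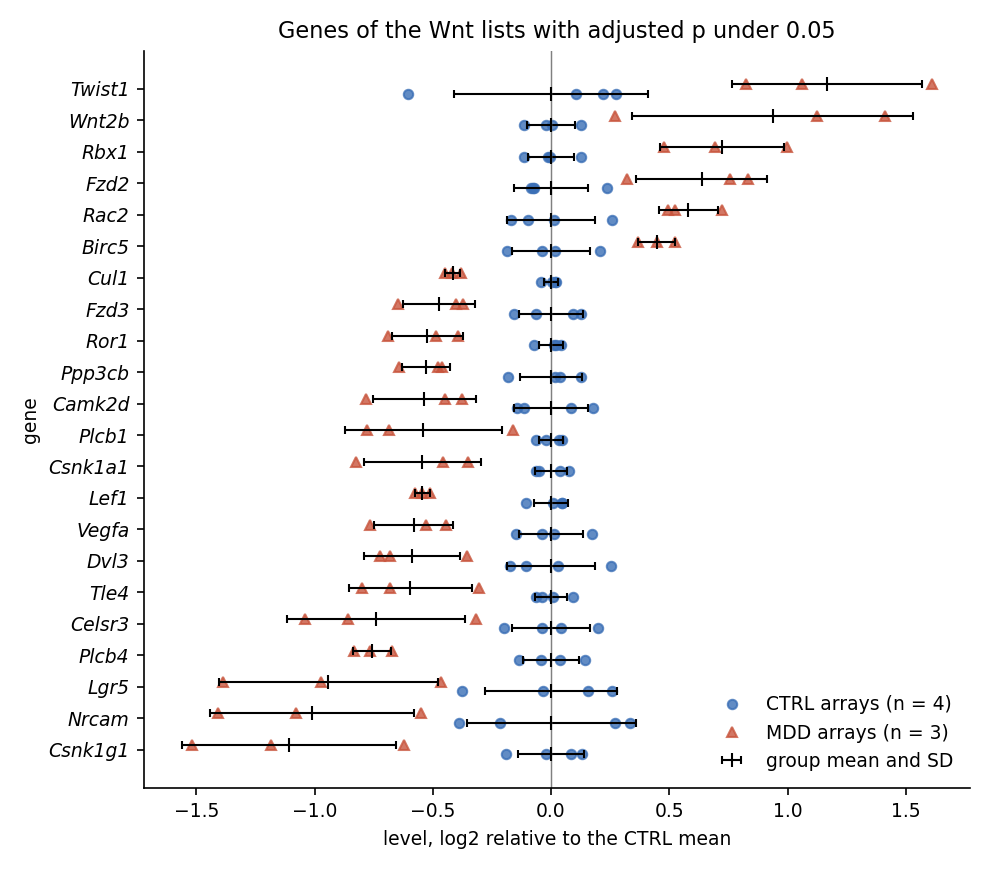
Level of the 22 named genes of the Wnt lists with an adjusted p under 0.05 on each array, in log2 relative to the CTRL mean, with group means and SD (n = 4 CTRL circles, n = 3 MDD triangles). The MDD mean is lowest for Csnk1g1 at -1.11 and highest for Twist1 at 1.17, and for Wnt2b the SD is 0.59 in MDD and 0.10 in CTRL.

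Granule neuron markers were lower, with 1 of 19 measured members higher and 5 lower (1 and 9 adjusted over the list alone), a median log2 change of -0.38 and a camera adjusted p of 0.0151 (adjusted p = 0.670 with an estimated correlation). Snap25, a protein of vesicle fusion that the synaptic vesicle list also holds, was 1.85-fold lower (4.23 ± 0.07 in CTRL, 3.34 ± 0.33 in MDD, SD, adjusted p = 0.0132). Gabra6, the GABA receptor subunit gene typical of granule neurons, was 1.67-fold lower (SE of log2 0.18, adjusted p = 0.0268). It is also counted in the list of GABA and glycine receptors, so the lower calls of these lists are not independent. Fat2 was 1.62-fold, the potassium channel gene Kcnd2 1.37-fold and the transcription factor gene Pax6 1.36-fold lower, and Calb2 (calretinin) was 1.45-fold higher. The median of the list lay below that of all 10000 random lists matched on signal and gene length. Those leave out the correlation between members, estimated at 0.187 for this list.

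Camera with the preset correlation also called the lists of the synapse and of axon guidance lower. None of them passed with an estimated correlation (adjusted p = 0.670 to 0.748). Of 19 GABA and glycine receptor genes, 0 were higher and 4 lower (2 and 12 adjusted over the list alone, median -0.44, camera adjusted p = 0.00357, and adjusted p = 0.670 with an estimated correlation). Glra2, a glycine receptor subunit gene, was 2.28-fold lower (SE of log2 0.15, adjusted p = 0.00967). Of 46 genes of glutamate receptors and the excitatory synapse, 1 was higher and 5 lower (0 and 4 adjusted over the list alone, median -0.33, and -0.22 with normexp, camera adjusted p = 0.00677, and adjusted p = 0.670 with an estimated correlation). The AMPA receptor gene Gria2 was 1.72-fold lower, the scaffold gene Shank3 1.51-fold lower, and Grik4 was 1.34-fold higher. Of 41 genes of axon guidance and cell adhesion, 1 was higher and 9 lower (the same counts adjusted over the list alone, median -0.25, but -0.14 with normexp and -0.17 with the authors' deposited table, camera adjusted p = 0.00662, and adjusted p = 0.670 with an estimated correlation). Epha7 was 1.65-fold, Unc5b 1.49-fold, Sema5a 1.48-fold and Cdh8 1.44-fold lower, and the ephrin gene Efnb1 was 1.46-fold higher. Of 32 synaptic vesicle genes, 0 were higher and 5 lower (0 and 3 adjusted over the list alone, median -0.29, camera adjusted p = 0.0314, and adjusted p = 0.748 with an estimated correlation). The active zone gene Pclo was 1.78-fold, Sypl1 1.74-fold and Synpr 1.74-fold lower. The vesicle call was lost without CTRL replicate 3 (adjusted p = 0.0682) and without MDD replicate 1 (adjusted p = 0.206).

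The change followed gene length. Random lists matched to a list on signal and gene length had medians of -0.18 for GABA and glycine receptors, -0.14 for glutamate, -0.19 for axon guidance, -0.14 for planar cell polarity, -0.08 for synaptic vesicles, -0.08 for the beta-catenin core and 0.20 for oxidative stress. Among them the list's own median lay at percentile 0.175 for GABA and glycine receptors, 0.05 for glutamate, 16.8 for axon guidance, 0.56 for planar cell polarity, 0.18 for synaptic vesicles, 5.46 for the beta-catenin core, 85.9 for oxidative stress and 99.84 for microglia. Random lists leave out the correlation between members of a list. Across named genes, MDD minus CTRL correlated with gene length at a Spearman's rho of -0.40. Across all genes and unnamed probes tested, it correlated with mean signal at a rho of 0.30. Genes are not independent replicates in either. The shortest 1197 genes had a median log2 change of 0.21, with 316 genes higher and 35 lower. The longest 1197 had a median of -0.26, with 21 higher and 183 lower. Against the CTRL arrays, each MDD array showed the trend (rho of -0.30, -0.31 and -0.42), while each CTRL array against the other controls had a rho between -0.05 and 0.07. With each array's trend with gene length and signal removed, an alternative chosen after the trend was seen, 759 named genes were higher and 565 lower. The ribosomal, oxidative phosphorylation and granule lists then each had an adjusted p of 0.000519 and the microglial list 0.00923. The median shrank from 0.74 to 0.14 for ribosomal proteins, with 17 of 74 members higher (61 before). For oxidative phosphorylation it shrank from 0.64 to 0.20, with 12 of 68 members higher and 1 lower (47 and 0 before). It stayed for granule markers (-0.38 before, -0.41 after) and microglia (0.44 before, 0.46 after). The call was lost for the lists of beta-catenin (adjusted p = 0.105), planar cell polarity (0.218), oxidative stress (0.411), glutamate (0.266), GABA and glycine (0.0921), synaptic vesicles (0.0921) and axon guidance (0.707). The beta-catenin median did not shrink (-0.187 before, -0.190 after), while the medians of the other lists that lost their call did. Its members called lower nevertheless went from 6 to 2, and its lower quartile from -0.47 to -0.33.

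**Figure D3:**
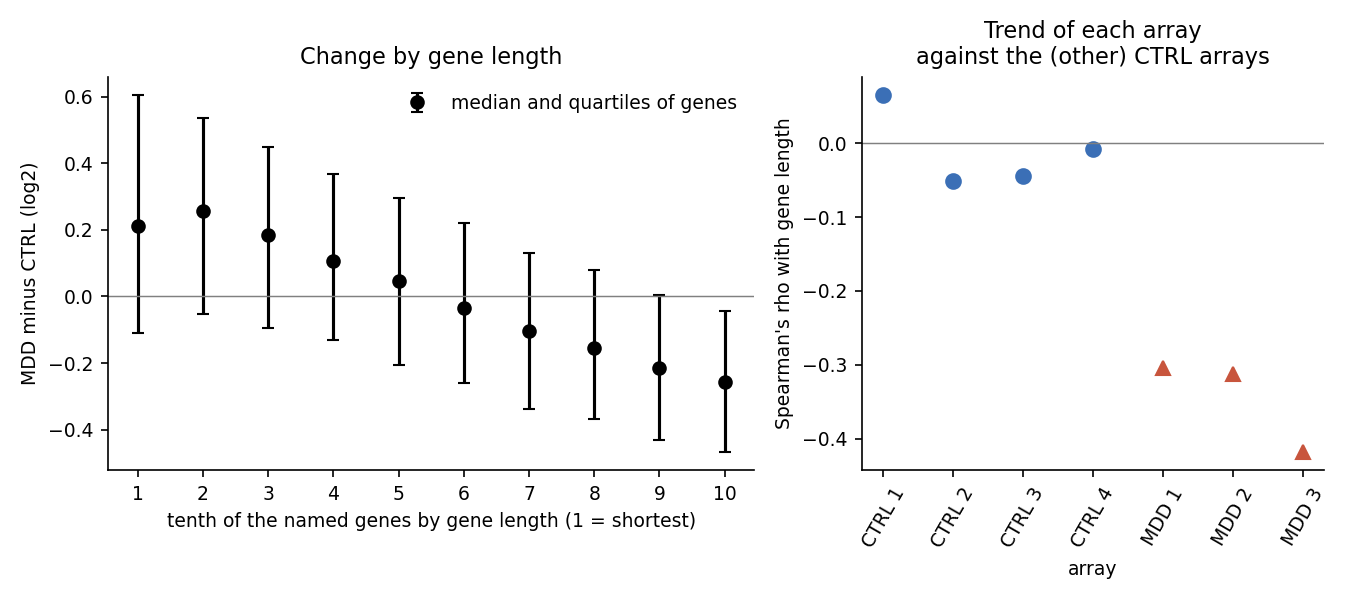
Left, MDD minus CTRL in log2 for named genes in 10 bins of genomic gene length, as the median with quartiles. Right, Spearman's rho between gene length and each array's deviation from the CTRL arrays (from the other 3 for a CTRL array), with CTRL as circles and MDD as triangles. The medians go from 0.21 in the shortest bin to -0.26 in the longest, with the highest, 0.26, in bin 2, and the MDD arrays lie between -0.42 and -0.30.

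Lists on the nutrients missing from the diet moved both ways and were not called. Of 42 genes of one-carbon and methionine metabolism, 8 were higher and 4 lower (9 and 5 adjusted over the list alone, median 0.13, camera adjusted p = 0.526). Genes of serine synthesis were among the higher ones, with Phgdh at 1.90-fold (4.04 ± 0.10 in CTRL, 4.96 ± 0.35 in MDD, SD, adjusted p = 0.0135) and Psph at 1.54-fold. Cbs, which takes homocysteine towards cysteine, rose 1.82-fold (SE of log2 0.18, adjusted p = 0.0173), and the mitochondrial folate gene Aldh1l2 rose 1.94-fold. Amn, which takes part in vitamin B12 uptake, was 1.60-fold higher. Lower were the mitochondrial folate carrier gene Slc25a32 (1.54-fold), Lmbrd1, which exports vitamin B12 from lysosomes (1.41-fold), and Mtr, the B12-dependent methionine synthase gene (1.65-fold, well above background on 4 of 4 CTRL and 1 of 3 MDD arrays). Of 25 choline and phospholipid genes, 2 were higher and 3 lower (2 and 3 adjusted over the list alone, median -0.14, camera adjusted p = 0.526). Gpcpd1, which releases choline from glycerophosphocholine, was 2.15-fold lower (SE of log2 0.16, adjusted p = 0.00991) and Etnk1 1.67-fold lower, while the phosphatidylserine synthase genes Ptdss2 (log2 0.59) and Ptdss1 (1.38-fold) were higher. Of 24 DNA and histone methylation enzymes and related genes, 2 were higher and 1 lower (2 and 1 adjusted over the list alone, median -0.13, camera adjusted p = 0.620). Prmt1 rose 1.77-fold and Mbd3 1.36-fold, and Tet3 was lower (log2 -0.59). Of 21 imprinted genes, 2 were higher and 2 lower (3 and 2 adjusted over the list alone, median 0.02, mean -0.08, camera adjusted p = 0.895). Dio3 rose 1.94-fold and Ndn by a log2 of 0.58, and Ube3a and Plagl1 were 1.57-fold and 1.53-fold lower.

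No other cell type list was called. Purkinje markers went both ways, with 3 of 17 higher and 2 lower (4 and 3 adjusted over the list alone, median -0.04, mean 0.06, camera direction up, and down with quantile normalization, normexp and the authors' deposited table, adjusted p = 0.896). Pvalb rose 1.59-fold and Slc1a6 1.67-fold, while Calb1 was 1.48-fold lower. Inhibitory interneuron markers had 1 of 18 higher and 3 lower (2 and 3 adjusted over the list alone, median -0.25, camera adjusted p = 0.508). Gad1 was 1.31-fold lower (log2 change of -0.12 for its other probe), Gad2 lower by a log2 change of -0.59 and Sst 1.76-fold higher. Granule precursor and proliferation markers had 3 of 24 higher and 0 lower (1 and 0 adjusted over the list alone, median 0.13, camera adjusted p = 0.380), among them Mcm3 (1.53-fold) and Cdk1 (1.44-fold). Myelin markers had 0 of 23 higher and 4 lower (1 and 4 adjusted over the list alone, median -0.13, camera adjusted p = 0.231), with Ermn 1.59-fold and Mobp 1.49-fold lower (log2 change of -0.05 for the other probe of Mobp). This list passed as lower with quantile normalization (adjusted p = 0.00687), with the authors' deposited table (adjusted p = 0.00736) and without MDD replicate 3 (adjusted p = 0.0296). Sox6, at 1.40-fold lower and well above background on 1 of 3 MDD arrays, was the only 1 of 12 oligodendrocyte precursor markers that passed (0 and 0 adjusted over the list alone, median -0.17, camera adjusted p = 0.526). Astrocyte and Bergmann glia markers had 2 of 21 higher and 1 lower (2 and 1 adjusted over the list alone, median 0.11, but -0.08 with quantile normalization and -0.02 with the authors' deposited table, camera adjusted p = 0.717), with Timp4 1.65-fold higher and Ptprz1 1.64-fold lower. Endothelial and mural markers had 2 of 19 higher and 0 lower (2 and 0 adjusted over the list alone, median 0.02, camera adjusted p = 0.654), Cldn5 at 1.60-fold and Myl9 at 1.62-fold. Markers of tissues next to the cerebellum varied between arrays of one group. Choroid plexus markers had 0 of 17 pass in either direction (0 and 0 adjusted over the list alone, median 0.08, camera adjusted p = 0.620), with list means relative to CTRL of 0.54, -0.54 and 0.58 on the MDD arrays. Meningeal markers had 2 of 21 higher and 0 lower (5 and 1 adjusted over the list alone, median 0.33, camera adjusted p = 0.130), with Mgp 1.52-fold higher. That list passed without MDD replicate 2 (adjusted p = 0.00576) and without CTRL replicate 4 (adjusted p = 0.0308). The choroid plexus list also passed without MDD replicate 2 (adjusted p = 0.00832). Blood cell markers had 0 of 11 pass (0 and 0 adjusted over the list alone, median 0.28, camera adjusted p = 0.533). Markers of brainstem, midbrain and forebrain had 0 of 12 pass (0 and 0 adjusted over the list alone, median 0.13, camera adjusted p = 0.849).

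Of the remaining 8 lists none was called. Cytoskeleton genes had 9 of 40 higher and 2 lower (9 and 2 adjusted over the list alone, median 0.09, but -0.23 with quantile normalization and -0.18 with the authors' deposited table, camera adjusted p = 0.209). The tubulin genes Tubb2b (1.81-fold), Tuba1a (1.81-fold) and Tubb4b (1.78-fold) were among the higher ones, and with quantile normalization the adjusted p was 0.0685 for the log2 change of Tubb2b and 0.259 for the log2 change of Tubb4b. Immediate early genes had 5 of 25 higher and 0 lower (5 and 1 adjusted over the list alone, median 0.22, camera adjusted p = 0.322), with Fosb at 2.18-fold and Junb at 1.64-fold. Inflammation and interferon genes had 4 of 33 higher and 2 lower (3 and 2 adjusted over the list alone, median 0.25, camera adjusted p = 0.140). The immunoproteasome genes Psmb8 and Psmb9 rose 2.44-fold and 1.92-fold. The interferon-induced genes Mx1 and Ifit2 were lower, Mx1 by 1.79-fold and Ifit2 by at least 2.17-fold. That bound equals the estimate for Ifit2 (SE of log2 0.25), which was not well above background on any MDD array. Apoptosis and p53 targets had 3 of 24 higher and 0 lower (1 and 0 adjusted over the list alone, median 0.13, camera adjusted p = 0.558), with Bax at 1.72-fold. Growth factor signalling had 0 of 35 higher and 3 lower (0 and 0 adjusted over the list alone, median -0.16, camera adjusted p = 0.276), with Igf1r 1.48-fold lower. Nuclear hormone signalling had 2 of 30 higher and 0 lower (2 and 0 adjusted over the list alone, median -0.19, camera adjusted p = 0.397). Endoplasmic reticulum stress genes had 1 of 26 higher and 1 lower (1 and 0 adjusted over the list alone, median -0.02, camera direction up, and down with quantile normalization, normexp and the authors' deposited table, adjusted p = 0.895), Sdf2l1 at 1.83-fold higher and Dnajb9 at 1.38-fold lower. Myelin lipid and cholesterol synthesis had 2 of 27 higher and 0 lower (1 and 0 adjusted over the list alone, median -0.11, camera adjusted p = 0.654), Pmvk at 1.49-fold and Fdps at 1.43-fold.

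The largest single rises were of Ascl3 (5.88-fold), Plac9 (3.81-fold), Cela3b (3.44-fold), Rplp1 (3.24-fold), the linker histone gene H1f1 (3.23-fold), Rplp1l1 (3.23-fold), Rpl39l1, RT1-CE10, a class I histocompatibility gene (3.11-fold), Cavin1 (3.02-fold), S100a6 (2.93-fold), Gpx1 (2.82-fold) and Prp25l1 (2.80-fold). Of these, Cela3b was well above background on 2, RT1-CE10 on 3 and Cavin1 on 1 of the 4 CTRL arrays. Rpl39l1 was not well above background on any CTRL array and was at least 3.16-fold higher, a bound that equals its estimate (SE of log2 0.42). Such bounds set the brighter group's mean against the higher of the probe's own signal and the lowest signal well above background on each array of the dimmer group. They leave out the spread between arrays. Ascl3 varied widely in CTRL (-4.21 ± 1.55, SD, n = 4), and the limma adjusted p for the log2 change of Ascl3 went from 0.0407 to between 0.0715 and 0.0986 when any 1 array other than CTRL replicate 1 was left out. The largest falls were in dim probes. Mpc1l (3.23-fold), Gosr1 (2.93-fold), Sbsn (2.82-fold), Rtp3 (2.62-fold), Virma (2.59-fold) and Defa5 (2.52-fold) were well above background on 4 of 4 CTRL arrays and 1 of 3 MDD arrays, and Htr2b, a serotonin receptor gene (2.84-fold), on 2 of 3. Slc10a1, Fam228a and Dpyd (the last on 3 of 4 CTRL arrays) were not well above background on any MDD array and were at least 2.77-fold, 2.39-fold and 2.16-fold lower. The haptoglobin gene Hp and Far1, an enzyme gene of ether lipid synthesis, were above background on all arrays and were 2.85-fold and 2.55-fold lower, with adjusted p of 0.0345 and 0.0330.

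The arrays separated by diet on the first principal component, which held 50.4% of the variance. CTRL arrays lay at -28.9 ± 7.30 (SD, n = 4) and MDD arrays at 38.6 ± 23.8 (SD, n = 3), a difference with the smallest exact permutation p that 35 splits allow (two-sided p = 0.0286). MDD replicate 2 lay nearest to CTRL. Pairwise correlations across genes ran from 0.989 to 0.994 within CTRL, 0.985 to 0.989 within MDD and 0.968 to 0.990 between groups. Of 5 array quality measures, which were background, signal, share of spots above background and the slope and level of spike-in controls, 0 passed (exact permutation test, adjusted p = 0.371 for each), but with 35 splits a single differing measure could not have passed after adjustment. The smallest p was that of the level of spike-in controls relative to the 75th percentile, at -1.19 ± 0.57 (SD, n = 4) in CTRL and -0.43 ± 0.66 (SD, n = 3) in MDD (exact permutation p = 0.143 before adjustment).

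**Figure D4:**
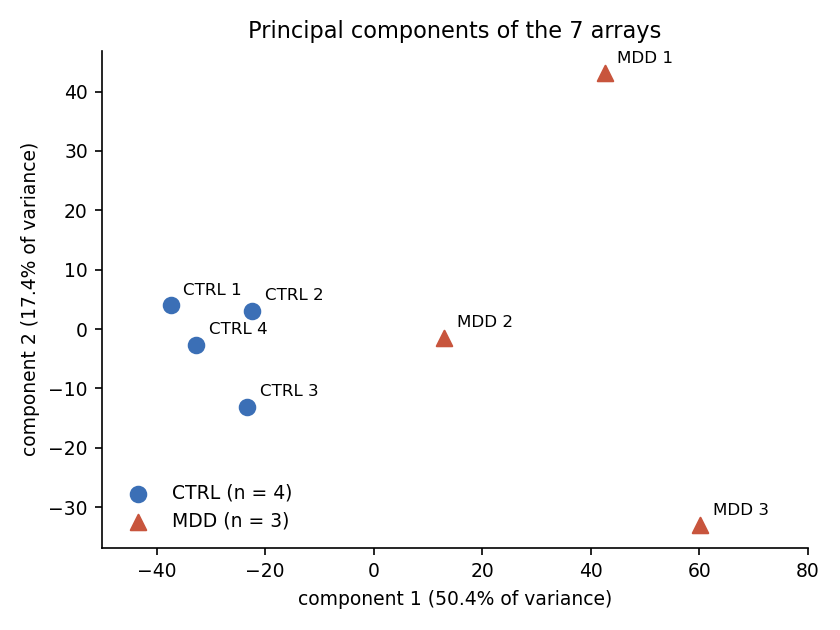
First and second principal components of all tested genes for the 7 arrays, with CTRL as circles (n = 4) and MDD as triangles (n = 3) and the share of variance on each axis. The CTRL arrays lie between -37.4 and -22.4 on component 1 and the MDD arrays between 13.0 and 60.1.

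All 7 arrays shared 1 slide and 1 scan, but the MDD arrays all lay in row 2 with CTRL replicate 4 as the only control there. With slide row as a block, which sets MDD against that array alone, limma called 0 genes higher and 2 lower (4067 at an unadjusted p under 0.05, against 7758 without the block). Those were P4ha3 and an unnamed probe, named here after their values were seen, and both rested on CTRL replicate 4, where P4ha3 stood at 5.10 and on the other 6 arrays between -5.53 and -4.14. With that block 10 of the 11 lists passed, and oxidative stress had an adjusted p of 0.0567. Leaving out 1 control moved the counts of higher and lower genes to 1393 and 488 (CTRL replicate 1), 1339 and 598 (replicate 2), 1070 and 331 (replicate 3) or 779 and 213 (replicate 4), and the lower count was 564, 2328 and 885 without MDD replicate 1, 2 and 3. Other groupings of the 7 arrays into 4 and 3 called at most 2 genes. They gave up to 15 shifted lists, against 11 for the diet grouping, and each grouping with 11 or more kept MDD replicates 1 and 3 on one side.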

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

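The comparison of choroid plexus, meningeal and blood markers over arrays below was chosen after the values were seen. Of 236 values examined over the 4 CTRL arrays (array measures, list means, component 1 and named genes), 11 (4.66%) had 1 array far from the other 3, by a gap that Dixon's test for 4 samples takes as an outlier. Chance gives about 1 in 20. Of these 11, CTRL replicate 1 accounts for 5, replicate 2 for 4 and replicate 4 for 2.

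CTRL replicate 1 stood apart for the mean of the blood cell markers, at -0.65 relative to the CTRL mean where the others lay between 0.16 and 0.30. On the same array Ascl3 stood at -1.91, where the others lay between -5.29 and -4.78. Without this array the rise of Ascl3 was 3.32 on the log2 scale. Gosr1 stood at -3.81 (others -5.31 to -5.09), Virma at -4.85 (others -5.49 to -5.44) and Wnt7a at -1.12 (others -0.81 to -0.78). CTRL replicate 2 stood apart for the mean of the planar cell polarity and Wnt calcium list, at -0.070 (others 0.018 to 0.032), for Ptdss1 at 2.37 (others 2.22 to 2.24), Rps19 at 3.81 (others 3.727 to 3.732) and Irs1 at -5.12 (others -4.93 to -4.90). CTRL replicate 4 stood apart for Fzd2 at -4.23 (others -4.55 to -4.54) and Gria2 at 0.10 (others -0.11 to -0.09).

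The blood marker mean moved with the choroid plexus mean, which also moved with the meningeal mean. Blood and meningeal means were not compared with each other. Over the 7 arrays, the choroid plexus mean correlated with the meningeal mean without shared genes at a Pearson's r of 0.891 (exact permutation p = 0.0103) and a Spearman's rho of 0.929 (exact permutation p = 0.00675), and at 0.957 without the 2 arrays farthest from the median. With the blood mean, r was 0.869 (exact permutation p = 0.0109), rho 0.893 (exact permutation p = 0.0123), and r without the 2 farthest arrays 0.683, so this relation rests in part on those arrays. Adjusted over these 2 relations, p was 0.0109 for each. The median pairwise correlation of the 17 measured choroid plexus genes, 4 of which another list also holds, was 0.667, above 100% of 10000 random lists matched on signal, and Ttr, the most abundant of them, stood at 6.79 ± 0.19 (SD, n = 4) in CTRL and 7.51 ± 0.64 (SD, n = 3) in MDD. Choroid plexus carried along in the dissection may therefore account for the variation of these genes, as a hypothesis. The differences between the diets missed the threshold (exact permutation p of 0.600, 0.229 and 0.486 for the choroid plexus, meningeal and blood means), which does not show that they are absent, and a difference between pups in the activity of these genes stays open.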

How the results depend on the processing

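The removal of trends with gene length and signal and the test of named genes only were chosen after seeing the data, and where a value differs below the cause was not tested unless stated. The gap between the groups on component 1 (67.5) had the smallest exact permutation p, 0.0286, also with quantile normalization (62.8), normexp (52.7) and the filter on all 7 arrays (61.7). Signal over background limits the size of the falls of Slc10a1, Fam228a and Dpyd to bounds, while a filter on all 7 arrays left the counts at 2784 higher and 1729 lower.

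Counts of genes (2534 higher and 1543 lower) moved by over 1.5 times for genes lower in MDD at an adjusted p under 0.1 (3009), with normexp (875) and with array weights (808). Without a filter, where 27455 genes are tested, they were 1205 and 388. With slide row as a block, limma called 0 and 2 (4067 at an unadjusted p under 0.05). With named genes only, where fewer genes are tested, they were 1392 and 845, then 942 and 649 with the length trend removed and 759 and 565 with length and signal trends removed. Leaving out 1 array at a time gave 779 to 2904 higher and 213 to 2328 lower genes, lowest without CTRL replicate 4 and highest without MDD replicate 2. All calls shared with these alternatives kept their sign.

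Same-numbered CTRL and MDD replicates deviated with correlations of 0.0885, -0.150 and 0.242, and not every sample correlated best with its own number. So few correlations neither show that the numbers pair the samples nor exclude it. With the replicate block, which leaves out the unmatched CTRL replicate 4 and keeps 2 residual degrees of freedom, limma called 0 higher and 0 lower genes (smallest adjusted p 0.0614, 6155 at an unadjusted p under 0.05), the beta-catenin list had an adjusted p of 0.0812 and the meningeal list passed at 0.0203. The other 36 lists kept their side of the threshold under that block.

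Of 4 lists called higher and 7 lower, 0 and 0 passed with an estimated correlation, where the adjusted p was 0.746 for beta-catenin, 0.748 for synaptic vesicles and 0.670 for the other 9. Fry called 6 higher and 4 lower. It lost beta-catenin (adjusted p = 0.0885), glutamate (0.0538), synaptic vesicles (0.195) and GABA and glycine receptors (0.0653), and added Wnt target genes (0.0492, lower), granule precursors (0.0264, higher) and cytoskeleton (0.0256, higher, though camera gave it as lower with quantile normalization and the authors' deposited table, at adjusted p of 0.117 and 0.239). Fry does not compare a list with other genes. Oxidative stress lost its call with quantile normalization (0.112), the authors' deposited table (0.0599) and slide row as a block (0.0567). Myelin markers passed as lower with quantile normalization (0.00687) and the authors' deposited table (0.00736), and inflammation passed without a filter (0.0470). With the length trend removed 1 lower list was called, and the adjusted p was 0.290 for beta-catenin, planar cell polarity and synaptic vesicles, 0.209 for oxidative stress, 0.557 for glutamate, 0.192 for GABA and glycine and 0.660 for axon guidance. With length and signal trends removed 1 lower list was called, and the adjusted p was 0.105 for beta-catenin, 0.218 for planar cell polarity, 0.0921 for synaptic vesicles and for GABA and glycine, 0.411 for oxidative stress, 0.266 for glutamate and 0.707 for axon guidance. For beta-catenin the median stayed (-0.187 before, -0.190 after), though its members called lower went from 6 to 2. For the other lists named here the median shrank.

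Leaving out 1 array at a time, the adjusted p ran from 0.0196 to 0.119 for beta-catenin, 0.0147 to 0.206 for synaptic vesicles, 0.00419 to 0.117 for oxidative stress, 0.00832 to 0.969 for choroid plexus, 0.00576 to 0.543 for meninges and 0.0296 to 0.652 for myelin. Ribosomal proteins, oxidative phosphorylation, microglia and granule cell markers stayed past the threshold with every camera alternative at the preset correlation. With quantile normalization and the authors' deposited table their medians were 0.25 and 0.30 for ribosomal proteins (0.74 before), 0.18 and 0.26 for oxidative phosphorylation (0.64 before), 0.46 and 0.41 for microglia (0.44 before) and -0.47 and -0.38 for granule cells (-0.38 before). Among lists not called, the authors' deposited table moved the median from -0.29 to -0.08 for Wnt targets, 0.28 to 0.098 for blood cells, 0.25 to 0.13 for inflammation, 0.22 to 0.12 for immediate early genes and -0.25 to -0.15 for inhibitory interneurons.

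Among named genes, the log2 change of Ndn (-0.031) and the log2 change of Tubb2a (-0.027) reversed with length and signal trends removed, where 75 others lost their call. Lost calls numbered 39 with quantile normalization, 49 with normexp, 23 with the authors' deposited table and 9 with the mean of a gene's probes. With slide row as a block 162 were lost, as were 162 with the replicate block. Leaving out 1 array lost 72, 80, 92 and 106 for CTRL replicates 1 to 4 and 70, 16 and 46 for MDD replicates 1 to 3.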

Other observations

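The gene families of the next paragraph, the tests on slide position and choroid plexus, the removal of trends and the weighing of it against matched random lists were chosen after the data were seen.

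Beyond the fixed lists, 13 families picked by gene symbol were tested with camera at the preset correlation, adjusted over the families, and 0 of them passed with an estimated correlation (smallest adjusted p 0.311). Of 21 histone genes 11 were higher and 0 lower (median 0.50, adjusted p = 8.12e-05, and 0.311 with an estimated correlation), among them H2ac4 (2.74-fold) and H2aj (2.35-fold). Of 12 genes of S100 calcium-binding proteins 6 were higher and 0 lower (median 0.76, adjusted p = 0.000127, and 0.311 with an estimated correlation), among them S100a13 (2.51-fold) and S100a4 (2.31-fold). Mitochondrial ribosomal proteins had 25 of 67 higher and 0 lower (median 0.34, adjusted p = 1.51e-07, and 0.311 with an estimated correlation), with Mrpl20 at 1.90-fold. Proteasome subunits had 12 of 36 higher and 0 lower (median 0.36, adjusted p = 0.000127, and 0.366 with an estimated correlation), with Psmb4 at 2.18-fold. The proteasome call was lost with quantile normalization (median 0.13, adjusted p = 0.120), and its median was 0.19 with the authors' deposited table. Zinc finger genes with Zfp symbols had 4 of 153 higher and 19 lower (median -0.27, and -0.17 with the authors' deposited table, adjusted p = 0.000127, and 0.311 with an estimated correlation), with Zfp800 2.11-fold lower. Protocadherins had 0 of 32 higher and 6 lower (median -0.43, and -0.15 with normexp and -0.22 with the authors' deposited table, adjusted p = 0.000127, and 0.311 with an estimated correlation), with Pcdhgb7 2.38-fold lower. Calcium channel genes had 0 of 23 higher and 5 lower (median -0.33, and -0.17 with normexp, adjusted p = 0.00256) and potassium channel genes 0 of 26 and 4 (median -0.25, and -0.14 with normexp and the authors' deposited table, adjusted p = 0.00930), with 0.366 for both with an estimated correlation. Spliceosomal proteins (adjusted p = 0.0552), olfactory receptors (0.103), kinesins (0.128), translation initiation factors (0.536) and tRNA synthetases (0.578) did not pass, and the last 2 turned from higher to lower with quantile normalization and the authors' deposited table. With the trends with gene length and signal removed, the adjusted p was 1.11e-05 for zinc finger genes, 0.000676 for protocadherins and for S100 genes, 0.0228 for mitochondrial ribosomal proteins, whose median shrank from 0.34 to 0.11, and 0.00683 for olfactory receptors (lower, though their median was 0.05 with quantile normalization before removal). The calls ended for histones (adjusted p = 0.0711, median 0.50 to 0.32), proteasome subunits (0.0893, 0.36 to 0.10), calcium channels (0.0893, -0.33 to -0.19) and potassium channels (0.198, -0.25 to -0.08).

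The lists differ in how much of their shift went with a trend of the arrays with gene length and signal. With the trend removed, camera's adjusted p at the preset correlation went from 2.32e-26 to 0.000519 for ribosomal proteins. It went from 5.10e-17 to 0.000519 for oxidative phosphorylation, from 0.0151 to 0.000519 for granule cell markers and from 0.00637 to 0.00923 for microglia. Before the removal, correlations between members were estimated at 0.558, 0.398, 0.187 and 0.156 for these lists in turn, above the preset 0.01. These p-values therefore do not exclude the trend. The median log2 change went from 0.74 to 0.14 for ribosomal proteins (quartiles 0.54 and 0.97 before, -0.01 and 0.38 after) and from 0.64 to 0.20 for oxidative phosphorylation (0.38 and 0.85 before, -0.02 and 0.43 after), so most of their size went with it. It stayed for granule markers (-0.38 before, -0.41 after, quartiles -0.52 and -0.11 before, -0.60 and -0.19 after) and microglia (0.44 before, 0.46 after, quartiles 0.11 and 0.84 before, 0.02 and 0.66 after). A lower share or activity of granule neurons and a changed state of microglia under the diet are candidate explanations, which were not tested in cells, and Cx3cr1 went against a plain rise in microglial number.

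For 5 lists the call ended and the median shrank to under 50% of its size. For axon guidance (adjusted p = 0.707, median -0.25 to -0.03, quartiles -0.47 and -0.06 before, -0.22 and 0.16 after) and oxidative stress (0.411, 0.31 to 0.14, quartiles 0.05 and 0.64, then -0.16 and 0.36) this fits the trend as a source, and their medians lay among those of random lists matched on signal and gene length (percentiles 16.8 and 85.9). The other 3 stay open, because their medians lay beyond most of the matched lists, at percentiles 0.05, 0.56 and 0.175. They were glutamate (0.266, -0.33 to -0.14, quartiles -0.46 and -0.02, then -0.27 and 0.12), planar cell polarity and Wnt calcium (0.218, -0.31 to -0.15, quartiles -0.47 and -0.12, then -0.30 and 0.03) and GABA and glycine receptors (0.0921, -0.44 to -0.16, quartiles -0.73 and -0.30, then -0.51 and -0.02). Random lists leave out the correlation between members of a list, estimated at 0.119, 0.0645 and 0.378 for these 3, so the percentiles do not exclude the trend. The other calls that ended lost less of their size and stay open. The beta-catenin list had a median of -0.19 before and after (adjusted p = 0.105, quartiles -0.47 and 0.08, then -0.33 and 0.06), and synaptic vesicles went from -0.29 to -0.16 (adjusted p = 0.0921, quartiles -0.43 and 0.05, then -0.48 and -0.05). Removing a trend also removes any effect of the diet that follows gene length, as one on long neuronal genes would, so these tests do not show that the shifts are technical.

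The source of the length trend itself is not settled. Scaling of the arrays is argued against, since the weakest rank correlation of the change with gene length over quantile, median and normexp processing was -0.376, although median scaling cannot move it. Position on the slide cannot be told apart from diet, because CTRL replicate 4, whose rank correlation was -0.00853 against -0.304 for the MDD array nearest to 0, is the only control in the row of the MDD arrays. RNA fragmentation stays open: the 2 brightest probes of a gene differed in their MDD minus CTRL change by a median of 0.157 over 2074 genes, more than in the median of the other splits (0.129) but less than in the highest (0.162). RNA integrity values, which the sources used here do not give, could decide it. An effect of the diet on transcripts of long genes is an open biological explanation and was not tested. Gene length here is genomic, and transcript length was not examined.

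Whether other groupings of the arrays give as much was examined over all 35 splits into 4 and 3. For the number of changed genes, 1 of the 35 splits, the real one, gave as many as 4077 and the highest other gave 2. Random assignment of single arrays is therefore argued against for this number, with the smallest share that 35 splits allow. The labels name no litters and the MDD arrays share a slide row, so chance differences between litters or array positions are not excluded. For the number of shifted lists the count of splits cannot exclude chance, since 8 of the 35 splits gave at least the 11 lists of the real one and the highest other gave 15. All 8 are among the 15 splits that keep MDD replicates 1 and 3, the arrays farthest from CTRL on component 1, on one side. The 20 splits that part them gave at most 10 lists. Whether these arrays share more of the diet's effect or another trait, such as their high choroid plexus means (0.54 and 0.58, against -0.54 for MDD replicate 2), was not tested.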
